A study of Homo sapiens with 8 samples.

How the data were processed

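Total RNA of 8 SK-N-MC cultures was measured on Affymetrix-type whole-transcript arrays, 4 with control siRNA and 4 with YAP1/TAZ siRNA. Per the labels' protocols, biotin-labelled cRNA was made with the GeneChip WT PLUS kit, and the replicates were separate cultures transfected and collected side by side. The siRNA was used at 10 nM for 72 h. The deposited values are log2 signals per transcript cluster, the array's unit for a gene locus, made with Transcriptome Analysis Console per the submitters' processing notes. The version, the summary algorithm, the between-array normalization and the genome build are not given in the sources used here, so no coordinates are printed. The deposited table held 67528 transcript clusters with 2 decimals and values from 2.27 to 19.93. That the scale is log2 was read from this range and from array medians between 4.34 and 4.49. A summary over many probes tends to compress fold changes, so the differences may understate changes in transcript number, above all near the lower end. How far signal lay above background is not given in the sources used here.

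Groups were taken from the sample titles. Of the clusters, 23781 had 1 gene symbol, 1543 had several and 42204 had none in the platform annotation. Only those with 1 symbol were used. Symbols were updated with RefSeq gene names for GRCh38.p14, 21497 through the Entrez identifier, 1974 through the symbol and 306 through a synonym, and 4 were kept as given. For the 528 genes with several clusters, the cluster with the highest mean over the 8 arrays was used. This left 22411 genes, 17151 of them protein-coding, with no filter on dim genes. Values were used as normalized by the submitters.

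Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, 6 residual degrees of freedom, 2.78 prior degrees of freedom), with Benjamini-Hochberg adjustment over 22411 genes and a threshold of 0.05. A difference of 1 on the log2 scale was the size threshold for a 2-fold change. YAP1 and WWTR1 were also tested with a 2-sided exact permutation test on the difference of means. The limma step was tested on simulated data with the real genes' means and spreads and 200 changed genes. It recovered 60% of genes changed by 0.5 and 89% of those changed by 1 on the log2 scale, with 8 false among 157 calls, and 0 calls when nothing was changed. The simulated noise was independent between genes and arrays. It lacked the shared displacement of control replicate 4 and YAP1/TAZ siRNA replicate 2 described below, so these rates may not hold for the real arrays.

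There were 23 gene lists, written from general knowledge of the pathways. The first 5 were primary: YAP/TAZ target genes, genes that EWS-FLI1 activates, genes that it represses, S phase and DNA replication genes, and mitosis genes. The others covered the Hippo pathway, actin and SRF targets, extracellular matrix, integrins, TGF-beta, interferon, unfolded protein and integrated stress response, p53, apoptosis, cholesterol synthesis, glycolysis and hypoxia, neural genes, histones, ribosomal proteins, and markers of epithelial, blood, neuroblastoma and fibroblast cells. Some genes, such as LOX, FN1 and BIRC5, belong to more than 1 list. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 23 lists, with an estimated correlation and with fry as alternatives. Members were counted at a limma adjusted p under 0.05 over all genes, and again adjusted over the list alone.

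Named genes were YAP1 and WWTR1, the 12 largest rises and the 12 largest falls among the changed genes, and up to 4 changed members of each list. A primary list would have added up to 2 changed members that went against its majority. The rises and falls were restricted to genes with every YAP1/TAZ siRNA array beyond every control array, a mean above the median of all genes (5.03), and a symbol that is neither a placeholder nor a pseudogene. This gave 26 genes. List members that did not change over all genes are given as examples, the 4 with the smallest p of a list that passed camera and the member with the smallest p of any other list. Those examples, the further members said to pass adjusted over a list alone, and NFKBIA, TNFAIP3, NR4A3, C3, VCAM1, SLC7A11, MIR32, IFI6, KRT25, PSAT1, CD83, CCL20, SLC7A5, HERPUD1 and those named with other treatments of the arrays that stood apart were chosen after their values were seen.

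The tests, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives chosen beforehand were the replicate number as a block, quantile normalization, centring each array on its median, leaving out genes at or below the median level, the mean of a gene's clusters, limma-trend with robust eBayes, array quality weights, testing every transcript cluster, and leaving out each array in turn. Added after seeing the data were leaving out control replicate 4 and YAP1/TAZ siRNA replicate 2, fitting that pair as a block, and the array median as a covariate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures, and statmod 1.5.0 within limma. Transcript clusters with several or no symbol were left out of the main test because they could not be given a gene name.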

Results

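RNA was measured on 8 whole-transcript arrays from SK-N-MC, an established Ewing sarcoma cell line. Ewing sarcoma is a tumour of bone and soft tissue driven by a fusion transcription factor, most often EWS-FLI1. YAP1 and TAZ, the latter encoded by WWTR1, are transcriptional co-activators that the Hippo kinase pathway restrains and that act through TEAD proteins. Cells of 4 cultures received a non-targeting control siRNA, and cells of 4 further cultures received a mix of siRNAs against YAP1 and TAZ. The siRNA concentration was 10 nM and the cells were collected at 72 h. The array medians lay between 4.34 and 4.49 on the log2 scale. Pearson correlations between arrays, across the 22411 genes tested, were 0.992 to 0.998. The number of arrays limits the precision of every value given. The spreads are those between cultures handled side by side, so they do not cover variation between separate experiments.

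Control replicate 4 and YAP1/TAZ siRNA replicate 2 lay apart from the other arrays along the first principal component, which held 46.0% of the variance. Their loadings were 0.59 and 0.57, against −0.31 to 0.071 for the others. One array of each group was displaced, so the displacement of this pair was not confined to 1 siRNA group. Among the other arrays, the YAP1/TAZ siRNA loadings (−0.31 to −0.25) all lay below the control loadings (−0.23 to 0.071). The first component was therefore not free of the comparison.

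**Figure D1:**
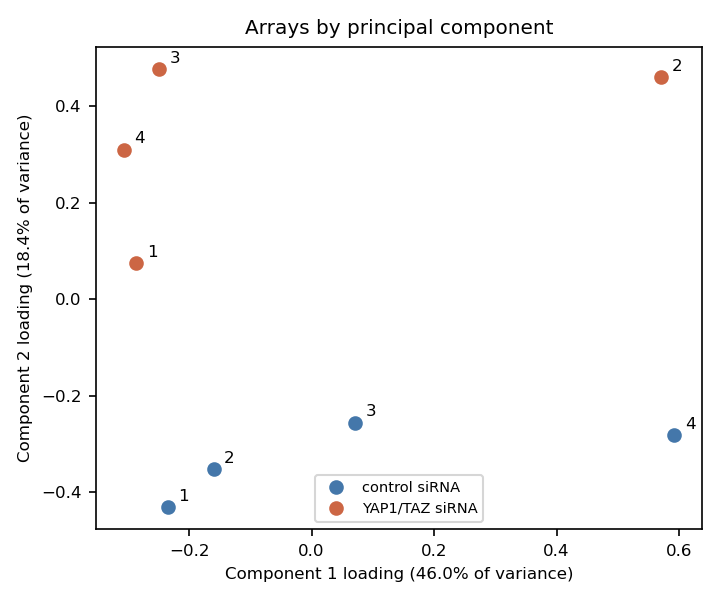
Loadings of the 8 arrays on the first principal component (x axis, 46.0% of the variance) and the second (y axis, 18.4%), coloured by siRNA and numbered by replicate. Control replicate 4 and YAP1/TAZ siRNA replicate 2 lie to the right, and the groups separate along the second component.

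YAP1 mRNA fell by 1.31 on the log2 scale in the YAP1/TAZ siRNA arrays (SE 0.053), from 7.68 ± 0.039 to 6.38 ± 0.070 (SD, n = 4 per group; limma adjusted p = 4.73e-05). On the linear scale this was 59.6% lower. WWTR1 fell by 0.62 (SE 0.064), from 6.48 ± 0.084 to 5.86 ± 0.080 (SD, n = 4 per group; limma adjusted p = 0.00898), which was 34.9% lower. Each of the 4 YAP1/TAZ siRNA arrays lay below each of the 4 controls for both genes. The 2-sided exact permutation p was 0.0286 for each, the smallest that 4 arrays against 4 can give. YAP1 was read from transcript cluster TC11000954.hg.1 and WWTR1 from TC03001890.hg.1. Without control replicate 1 the WWTR1 difference was −0.60, with a limma adjusted p of 0.0515.

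**Figure D2:**
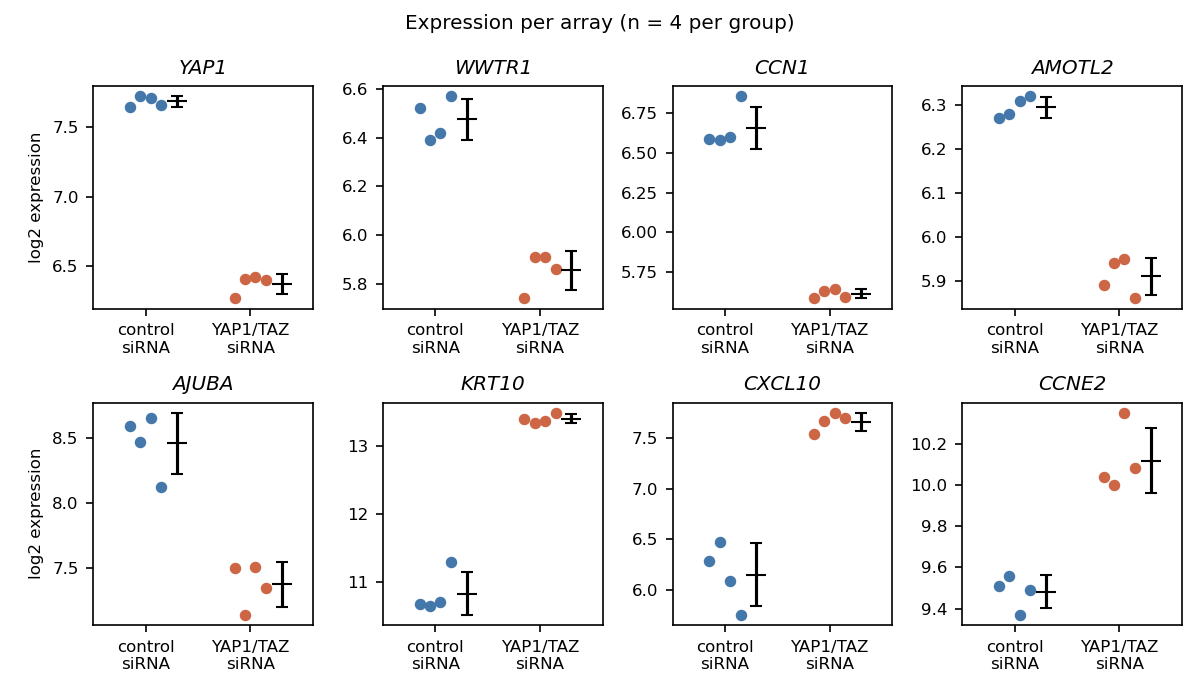
Log2 expression (y axis, a separate scale in each panel that does not start at 0) of 8 genes on each array, with the mean and SD of each group (n = 4) beside the points. YAP1, WWTR1, CCN1, AMOTL2 and AJUBA were lower on every YAP1/TAZ siRNA array than on any control array, and KRT10, CXCL10 and CCNE2 were higher.

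The comparison asks which transcripts change when YAP1 and TAZ are reduced in these cells. Among 22411 genes, 48 changed at a limma adjusted p under 0.05, of which 30 rose and 18 fell. KRT10, a type I keratin of differentiating epidermis, rose by 2.56 on the log2 scale (SE 0.14), from 10.84 ± 0.31 to 13.40 ± 0.065 (SD, n = 4 per group; limma adjusted p = 0.00026), a 5.91-fold rise. CXCL10, a chemokine induced by interferon, rose 2.83-fold, from 6.16 ± 0.31 to 7.66 ± 0.090 (SD, n = 4 per group; limma adjusted p = 0.00559). The other 4 genes that changed at least 2-fold fell, namely YAP1, AJUBA, MTA2 and CCN1. AJUBA, a LIM-domain protein that holds back LATS kinases, fell by 1.08 (SE 0.13, adjusted p = 0.0184). MTA2, a subunit of the NuRD chromatin complex, fell by 1.05 (SE 0.12, adjusted p = 0.0184). CCN1, a secreted matricellular protein and a known YAP target, fell by 1.05 (SE 0.071, adjusted p = 0.00122). AJUBA and MTA2 each passed in 2 of the 8 fits that left out 1 array, against 8 of 8 for YAP1 and CCN1. With each array centred on its median the limma adjusted p of AJUBA and MTA2 was 0.0906 and 0.0995. Over all alternatives it ran from 0.000579 to 0.092 for AJUBA and from 0.00124 to 0.147 for MTA2. With the replicate number as a block YAP1 and KRT10 passed, while CCN1, CXCL10, AJUBA and MTA2 did not.

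Of the further large rises, that of GDAP1, a mitochondrial outer membrane protein mutated in Charcot-Marie-Tooth disease, was 0.98 (SE 0.080). SLC17A7, a vesicular glutamate transporter, rose by 0.67 (SE 0.088). E2F2, a transcription factor of cell cycle entry, rose by 0.75 (SE 0.071), and CCNE2, a cyclin that activates CDK2, rose by 0.64 (SE 0.084). BOD1, which acts in chromosome attachment to the spindle, rose by 0.76 (SE 0.066). B3GALT1 and CPNE4 rose by 0.79 each, FAM111B by 0.76, WSB1 by 0.70 and PRR11 by 0.69. The limma adjusted p of these rises lay between 0.0035 for GDAP1 and 0.0417 for B3GALT1 and FAM111B. GDAP1, BOD1, E2F2 and WSB1 passed in 8 of the 8 fits that left out 1 array and CPNE4 in 7, but PRR11 and CCNE2 passed in 2 and B3GALT1, FAM111B and SLC17A7 in 1. With each array centred on its median CPNE4 (adjusted p = 0.0643), E2F2 (0.0522), B3GALT1 (0.108), FAM111B (0.1), SLC17A7 (0.138) and CCNE2 (0.1) missed the threshold, and FAM111B missed it without the arrays that stood apart (0.0541).

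Among the falls, ANXA1, a phospholipid-binding annexin, fell by 0.91 (SE 0.091), and LMO7, a LIM protein of cell junctions, fell by 0.82 (SE 0.088). LOX, the lysyl oxidase that cross-links collagen, fell by 0.61 (SE 0.090), and VIM, the intermediate filament vimentin, fell by 0.60 (SE 0.088). MAT2B, the regulatory subunit of methionine adenosyltransferase, fell by 0.68 (SE 0.055). CRYBG1 fell by 0.66 (SE 0.069), and LIPI, a lipase gene, fell by 0.63 (SE 0.070). The limma adjusted p ran from 0.0035 for MAT2B to 0.046 for LOX. MAT2B passed in 8 of the 8 fits that left out 1 array, ANXA1 in 7, CRYBG1 in 6, LMO7 in 5, LIPI in 4, LOX in 2 and VIM in 1. With each array centred on its median CRYBG1 (adjusted p = 0.081), LIPI (0.0966), LOX (0.151) and VIM (0.162) missed the threshold, and without the arrays that stood apart LOX (0.0673) and VIM (0.0524) did.

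All 48 genes had every YAP1/TAZ siRNA array on the same side of every control array. Selection by a low adjusted p makes this nearly certain, so it is no separate support for them. Of all genes tested, 1394 (6.22%) did so, where chance gives 2.86%. The median absolute log2 difference of the 48 was 0.63. At an unadjusted p under 0.05 there were 2314 genes. The count of 48 depended on single arrays and on the model. It was 12, 13, 20 and 24 without control replicates 1, 2, 3 and 4, and 22, 166, 19 and 17 without YAP1/TAZ siRNA replicates 1, 2, 3 and 4. Without both arrays that stood apart, a setting chosen after seeing the data, it was 188, with 44 of the 48 among them. YAP1, CCN1, MAT2B, NR4A3, TNFAIP3, WSB1, E2F2, BOD1, GDAP1, CXCL10 and KRT10 passed in each of the 8 fits that left out 1 array. The other 37 genes missed the threshold in at least 1, with 29 passing in at most 2 of the 8. With the replicate number as a block, an alternative chosen beforehand, only 3 genes passed, namely YAP1, KRT10 and ANXA1. CCN1, MAT2B, NR4A3, TNFAIP3, WSB1, E2F2, BOD1, GDAP1 and CXCL10 missed the threshold there. With each array centred on its median 17 genes passed, and after quantile normalization 72 passed, of which 37 rose and 35 fell.

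**Figure D3:**
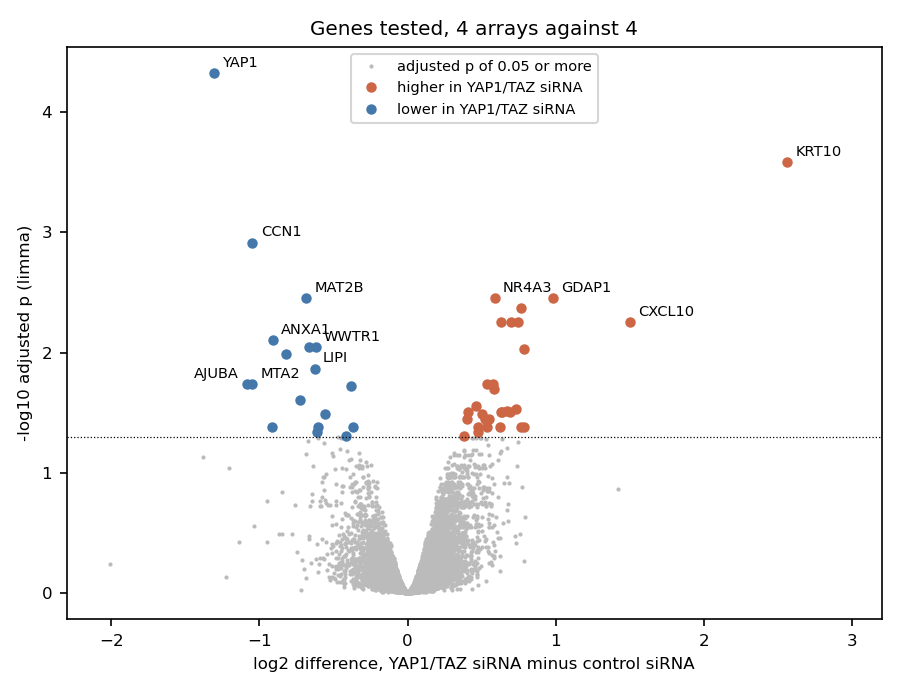
Log2 difference, YAP1/TAZ siRNA minus control siRNA (x axis), against the negative log10 of the limma adjusted p (y axis) for 22411 genes, 4 arrays against 4. The 30 genes that rose and the 18 that fell are coloured above the dotted line at 0.05, with KRT10 farthest to the right and YAP1 highest.

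Known YAP/TAZ target genes passed camera downward at its preset correlation. Of 22 measured, CCN1 and AMOTL2 fell over all genes tested, none rose and 20 did not pass. Adjusted over the list alone 4 fell, namely CCN1, AMOTL2, LATS2 and CCN2. AMOTL2, an angiomotin that binds YAP, fell by 0.38 (SE 0.046, limma adjusted p = 0.0188), but passed in 1 of the 8 fits that left out 1 array and not with each array centred on its median (adjusted p = 0.0761). LATS2, a Hippo kinase, differed by −0.39 (SE 0.069), and CCN2, a matricellular protein, by −0.44 (SE 0.10). The median difference was −0.076, with 17 genes below 0 and 5 above, and camera gave an adjusted p of 4.54e-05. The adjusted p was 0.132 with an estimated correlation.

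Genes that EWS-FLI1 activates passed camera upward at its preset correlation, with LIPI falling against them. Of 25 measured, LIPI fell and 24 did not pass over all genes. Adjusted over the list alone 6 rose and LIPI fell. PRKCB, a protein kinase C, differed by 0.46 (SE 0.090), LOXHD1 by 0.44 (SE 0.10) and PPP1R1A, a phosphatase inhibitor, by 0.32 (SE 0.081). The median difference was 0.13, with 20 genes above 0 (camera adjusted p = 0.000662; adjusted p = 0.3 with an estimated correlation). Genes that EWS-FLI1 represses had a median difference of −0.045 over 20 measured, with 14 below 0 (camera adjusted p = 0.0355; adjusted p = 0.191 with an estimated correlation). LOX fell and 19 did not pass over all genes. Adjusted over the list alone LOX fell and FN1, the matrix protein fibronectin, rose, with a difference of 0.53 (SE 0.14). This list's adjusted p was 0.149 without control replicate 1, 0.0548 without control replicate 2, 0.0558 without YAP1/TAZ siRNA replicate 2, 0.0803 without YAP1/TAZ siRNA replicate 4, 0.106 with the mean of a gene's transcript clusters, and 0.0653 without both arrays that stood apart.

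The mitosis and S phase lists passed camera upward at its preset correlation. For mitosis genes the median difference was 0.16 over 24 measured, with 22 above 0 (camera adjusted p = 1.69e-08; adjusted p = 0.191 with an estimated correlation). By limma 0 passed over all genes, 10 had an unadjusted p under 0.05, and 9 rose adjusted over the list alone. With the arrays that stood apart fitted as a block 6 rose over all genes (DLGAP5, KIF11, KIF23, MKI67, TOP2A and UBE2C), and without those arrays 3 rose (DLGAP5, KIF23 and TOP2A). Among the 9, UBE2C, which directs cyclins to degradation, differed by 0.46 (SE 0.072), KIF23, a kinesin of cytokinesis, by 0.40 (SE 0.086) and DLGAP5, a spindle protein, by 0.30 (SE 0.062). S phase and DNA replication genes had a median difference of 0.12 over 23 measured, with 22 above 0 (camera adjusted p = 0.000112; adjusted p = 0.403 with an estimated correlation). CCNE2 alone rose, both over all genes and adjusted over the list alone. UHRF1, which keeps up DNA methylation at replication forks, differed by 0.32 (SE 0.086) and MCM3, a subunit of the replicative helicase, by 0.34 (SE 0.12). Replication-dependent histone genes had a median of 0.13 over 12 measured and did not pass (camera adjusted p = 0.0921), with 0 members passing by limma over all genes or over the list alone and 1 at an unadjusted p under 0.05.

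Actin cytoskeleton and SRF target genes passed camera downward at its preset correlation, with a median of −0.086 over 20 measured and 15 below 0 (camera adjusted p = 0.000307; adjusted p = 0.191 with an estimated correlation). By limma 0 passed over all genes, 6 had an unadjusted p under 0.05, and TPM2, CNN2, TPM1 and CNN3 fell adjusted over the list alone. CNN2, a calponin, differed by −0.85 (SE 0.20), and TPM2, a tropomyosin, by −0.33 (SE 0.062). Extracellular matrix genes also passed downward there, with a median of −0.030 over 26 measured and 18 below 0 (camera adjusted p = 0.00601; adjusted p = 0.191 with an estimated correlation). LOX fell over all genes. Adjusted over the list alone 5 fell, including COL5A2 with −0.67 (SE 0.11) and SPARC, a collagen-binding glycoprotein, with −0.69 (SE 0.12), while TNC with 0.41 (SE 0.087) and FN1 rose. Without both arrays that stood apart the matrix list had a camera adjusted p of 0.0579.

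Interferon response genes passed camera upward at its preset correlation, with a median of 0.055 over 21 measured and 14 above 0 (camera adjusted p = 0.00542; adjusted p = 0.191 with an estimated correlation). CXCL10 rose over all genes. Adjusted over the list alone OAS3, RIGI and IFIH1 rose with it. OAS3, a sensor of double-stranded RNA that makes oligoadenylates, differed by 0.38 (SE 0.062), and RIGI and IFIH1, cytoplasmic RNA sensors, by 0.29 (SE 0.058) and 0.34 (SE 0.086). Neural genes, 20 measured with a median of 0.051, did not pass camera (adjusted p = 0.108), though ELAVL3, a neuronal RNA-binding protein, rose by 0.54 (SE 0.078, limma adjusted p = 0.0417) and SYT1 rose with it adjusted over the list alone. ELAVL3 passed in 1 of the 8 fits that left out 1 array, and its limma adjusted p was 0.067 after quantile normalization and 0.162 with each array centred on its median.

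Unfolded protein and integrated stress response genes passed camera downward at its preset correlation only, with a median of −0.21 over 16 measured and 14 below 0 (camera adjusted p = 4.54e-05; adjusted p = 0.3 with an estimated correlation). Fry gave an adjusted p of 0.207. By limma 0 passed over all genes and 9 had an unadjusted p under 0.05. The only member that passed adjusted over the list alone moved the other way, PDIA4, a disulfide isomerase of the endoplasmic reticulum, with 0.49 (SE 0.095). CHAC1, a glutathione-degrading enzyme, differed by −1.14 (SE 0.41), and its control arrays read 8.61, 7.40, 7.79 and 6.24, the last being control replicate 4. HSPA5, the chaperone BiP, differed by −0.55 (SE 0.20), with 11.74 on YAP1/TAZ siRNA replicate 2 against 12.53 to 12.57 on the other 3. Glycolysis and hypoxia genes passed camera upward at its preset correlation only, with a median of 0.065 over 22 measured and 19 above 0 (camera adjusted p = 0.0355; adjusted p = 0.56 with an estimated correlation). By limma 0 passed over all genes, 4 had an unadjusted p under 0.05, and ENO2, a neuronal enolase, rose adjusted over the list alone with 0.38 (SE 0.077). The glycolysis list's camera adjusted p was 0.302 without control replicate 4, and 0.158, 0.0972 and 0.169 without YAP1/TAZ siRNA replicates 1, 3 and 4. It was 0.088 after quantile normalization and 0.0974 with each array centred on its median.

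Other lists did not pass camera. Hippo pathway and TEAD partner genes had a median of 0.072 over 26 measured (adjusted p = 0.497). AJUBA fell over all genes, and adjusted over the list alone FRMD6 fell with it and AMOTL1 rose. Integrin and focal adhesion genes had a camera adjusted p of 0.302 over 22 measured, and PARVA, with a difference of −0.46 (SE 0.074), and ITGAV fell adjusted over the list alone, while 0 passed by limma over all genes and 3 had an unadjusted p under 0.05. Cholesterol synthesis genes had an adjusted p of 0.0683 over 14 measured, and SQLE, a monooxygenase of that pathway, with a difference of −0.38 (SE 0.080), fell adjusted over the list alone, while 0 passed by limma over all genes and 2 had an unadjusted p under 0.05. The adjusted p was 0.833 for 16 TGF-beta response genes, 0.689 for 15 p53 target genes, 0.302 for 16 apoptosis regulator genes and 0.643 for 18 ribosomal protein genes, with 0 members passing by limma over all genes or over the list alone in each. At an unadjusted p under 0.05 these lists held 3, 1, 5 and 0 members. For the integrin and ribosomal lists the median was 0.0012 while the mean and camera pointed down. For TGF-beta the median and mean lay above 0 and camera pointed down, and for p53 the mean was 0.0065 while the median and camera pointed down.

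Markers of other cell types did not pass camera either. The adjusted p was 0.0921 for 12 epithelial markers, 0.689 for 9 blood cell markers, 0.364 for 11 neuroblastoma and sympathetic markers and 0.302 for 12 fibroblast and mesenchymal markers. By limma 0 members of these lists passed over all genes, and 1, 1, 2 and 4 had an unadjusted p under 0.05. ALK, a receptor tyrosine kinase, differed by 0.68 (SE 0.14) and rose adjusted over the list alone, and LUM, a collagen-binding proteoglycan, differed by −0.54 (SE 0.14) and fell adjusted over the list alone. Camera's direction for blood cell markers turned after quantile normalization, while no other list did so there or with each array centred on its median. Of the 23 lists, 10 passed camera, 5 up and 5 down, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.132 and 6 lists had an unadjusted p under 0.05. By fry, which tests a list without comparing it with other genes, YAP/TAZ target, interferon response and neural genes passed, with adjusted p of 0.00274, 0.00663 and 0.00663.

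Counts of members past limma over all genes moved in other lists too when the arrays that stood apart were fitted as a block or left out, settings chosen after seeing the data. They were 3 and 3 for YAP/TAZ targets, 3 and 3 for EWS-FLI1-activated genes (PRKCB and LOXHD1 higher, LIPI lower in both), 2 and 0 for EWS-FLI1-repressed genes (FN1 higher, LOX lower), 3 and 2 for S phase, 2 and 1 for actin and 3 and 3 for interferon genes. For matrix genes 4 fell and 2 rose with the block. Without those arrays no matrix gene fell, LOX having a limma adjusted p of 0.0673, and the 1 that passed was TNC, which rose against its list. For integrin genes they were 2 and 1, and for glycolysis genes 3 and 1. For unfolded protein and integrated stress response genes PDIA4 passed with the block, and HERPUD1 and PSAT1 passed without those arrays. ALK of the neuroblastoma and sympathetic markers passed in both settings (limma adjusted p = 0.029 and 0.036). With the block, ID3 of the TGF-beta list and AMOTL1 of the Hippo list also passed. For the lists not named here, mitosis genes aside, the count was the same in both settings as on all 8 arrays.

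**Figure D4:**
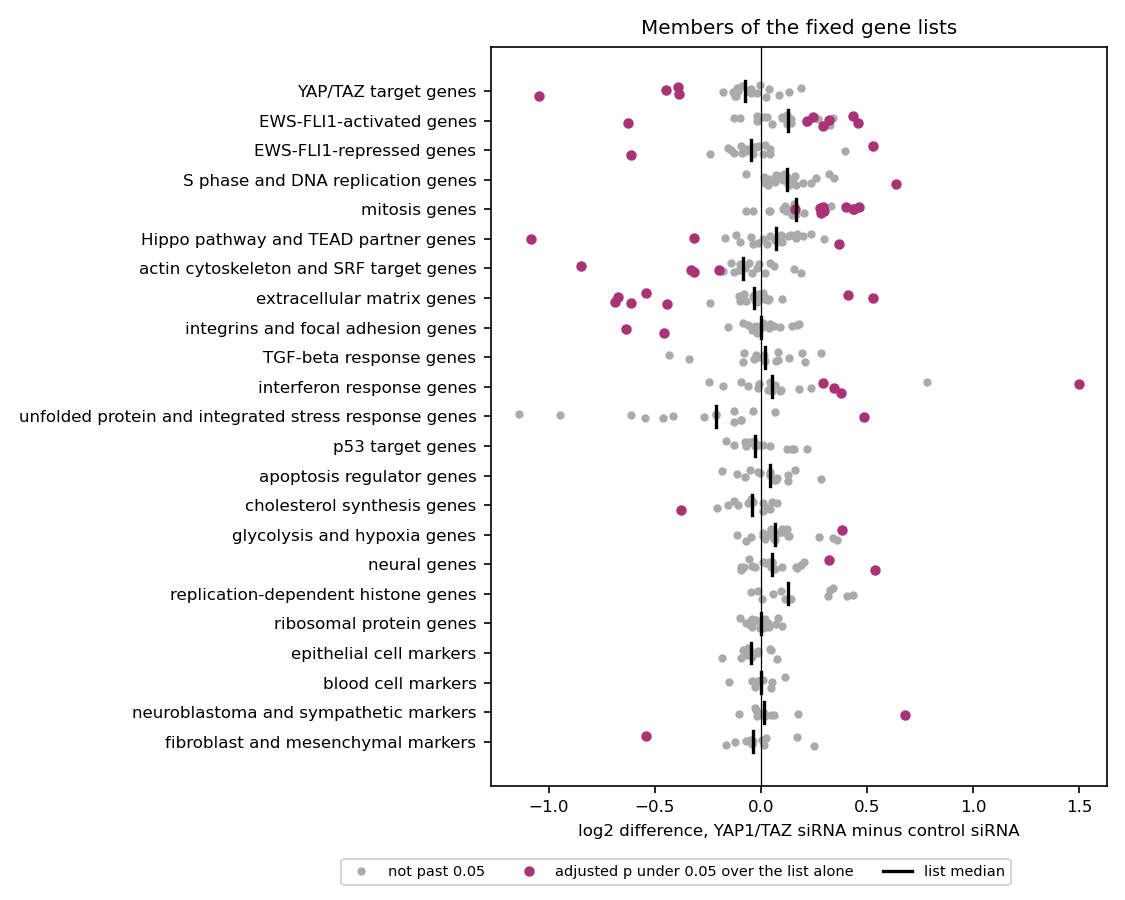
Log2 difference, YAP1/TAZ siRNA minus control siRNA (x axis), of each measured member of the 23 gene lists (y axis; vertical scatter within a list has no meaning), with the list median as a bar and members past 0.05 adjusted over the list alone in purple. The bar lies at 0.16 for mitosis genes and at −0.21 for unfolded protein and integrated stress response genes.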

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

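Of the tests weighed here, the correlation after quantile normalization was written down before its result was seen, and the others were chosen afterwards. A value was listed when the gap between 1 array and the nearest of the other 3 in its group, as a share of the group's range, exceeded Dixon's critical value. The 160 groups examined were the control and YAP1/TAZ siRNA groups of 78 genes (156 groups) and of the array medians and array correlations (4 groups). Of these 12 did so, all of them genes, where chance gives about 8, since about 1 in 20 groups does so by chance. That figure takes the groups as independent, but the genes share arrays, and some were chosen after their values were seen. Most of the listed values lay on control replicate 4 or YAP1/TAZ siRNA replicate 2, the arrays that stood apart.

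YAP1 read 6.27 on YAP1/TAZ siRNA replicate 1, against 6.40 to 6.42 on the other arrays of its group. BOD1 read 9.95 on YAP1/TAZ siRNA replicate 4, against 9.78 to 9.80. LOX read 8.44 on control replicate 3, against 8.71 to 8.75, and RPL27, a ribosomal protein, read 13.56 there, against 13.44 to 13.45. CCN1 read 6.86 on control replicate 4, against 6.58 to 6.60, and DLGAP5 read 12.81 there, against 12.61 to 12.64. On YAP1/TAZ siRNA replicate 2, FN1 read 10.08 (others 10.53 to 10.60), PARVA 6.53 (6.73 to 6.75), HSPA5 11.74 (12.53 to 12.57), SLC7A11 10.33 (11.01 to 11.09) and IFI6 5.99 (7.55 to 7.70).

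When every transcript cluster was tested with limma, 4 clusters with several or no gene symbol passed the threshold. TC05003061.hg.1 rose by 0.76 (SE 0.083), TC01006291.hg.1 fell by 0.82 (SE 0.084), and 2 more rose.

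Control replicate 4 and YAP1/TAZ siRNA replicate 2 deviated from their groups together, with r = 0.61 across genes, which are not independent replicates. The correlation stayed at 0.574 after quantile normalization, which argues against scaling that depends on brightness, and YAP1 in control replicate 4 lay 0.03 from the mean of the other controls, which argues against swapped labels. Genes of small nucleolar RNAs deviated by a median of 0.527 on YAP1/TAZ siRNA replicate 2 and 0.562 on control replicate 4, against −0.017 and −0.007 for protein-coding genes. A difference in RNA quality or labelling between these samples is therefore a candidate explanation that stays open. No biological explanation was tested, since the design puts 1 array in each group.

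KRT10 rose more than any other gene, and its lowest YAP1/TAZ siRNA array stood far above its control replicate 4, which read 11.3 against 10.65 to 10.71 on the other controls. Of its 6 nearest measured genes only KRT12 and KRT10-AS1 had a level above the median, a limit set after the values were seen. They differed by 0.085 and −0.115, which argues against signal from those genes, the antisense gene included. The dimmer neighbours decide nothing. KRT25, a dimmer keratin gene that was not among the 6, rose by 0.47 (SE 0.070, limma adjusted p = 0.0457), and signal shared with it was not tested. Without the arrays that stood apart the difference was 2.74, which argues against those arrays as the source. An off-target effect of the siRNA mix and an effect of losing YAP1 and TAZ both stay open, since 1 mix was used and neither was tested.

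The real split of the 8 arrays was the only 1 of 35 splits to give as many as 48 changed genes, and the highest other gave 0. The same was so for the 6 genes changed at least 2-fold (1 of 35, highest other 0). For the 10 gene lists past camera it was also 1 of 35, and the highest other was 9. Most other splits passed some lists too, so camera at its preset correlation of 0.01 called lists when the siRNA groups were mixed. The estimated correlation was 0.295 for mitosis, 0.383 for S phase, 0.409 for stress response and 0.356 for glycolysis genes. It was 0.02 for YAP/TAZ targets and 0.006 for interferon genes. For the counts of genes, 1 in 35 is the smallest share these splits can give, so they do not exclude chance. The other splits mix the siRNA groups, so any real siRNA effect widens the spread within their groups and lowers their counts. The list count led the next split by 1 list only, and 0 lists passed with an estimated correlation, so for the lists the count of splits is weak evidence against chance. Both splits with 9 lists put control replicate 4 and YAP1/TAZ siRNA replicate 2 in the same group.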

How the results depend on the processing

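YAP1 passed the threshold in every setting fitted at the gene level, with differences of −1.32 to −1.27 when 1 array was left out, and no gene in the text that had passed, and no list that had passed camera, changed direction in any setting. Signal over background is not given in the sources used here, so genes below the median level of 5.03, such as CCN2 and MIR32, have the least certain values. The settings that leave out both arrays that stood apart, fit them as a block or use the array median as a covariate were chosen after seeing the data.

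The count of changed genes, 48, was 17 with each array centred on its median, 82 with dim genes left out, 559 with array quality weights, 16 with every transcript cluster tested, 188 without both arrays that stood apart, 439 with that pair as a block and 419 with the array median as a covariate. Leaving out 1 array gave 12 to 166. The larger counts held 48 of the 48 genes with weights, the block or the covariate, and 44 without the pair. Fewer arrays or more tests lower the power, but the count was 166 without YAP1/TAZ siRNA replicate 2 and 188 without the pair. The array weights were lowest for the pair, 0.41 for control replicate 4 and 0.27 for YAP1/TAZ siRNA replicate 2. All counts of 166 or more came from settings that left out or weighted down arrays of the pair, or fitted the pair or the array median. Without control replicate 4 alone it was 24. The cause of the other moves was not tested. Genes changed at least 2-fold numbered 10 with weights and 10 without the pair. Quantile normalization gave 72 genes, 51.4% of them higher against 62.5%. The share higher was 78.2% with weights (437 higher, 122 lower), 76.6% without the pair, 76.1% with the pair as a block, 68.7% with the covariate, and 50% to 82.5% when 1 array was left out, the highest without YAP1/TAZ siRNA replicate 2 (137 higher, 29 lower). Of the 26 genes named by rule, 25 kept their call after quantile normalization and 12 with median centring.

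The labels number the replicates in both groups but do not say whether a number marks a shared plating or labelling day. Whether the numbers pair the arrays stays open. Correlations of the deviations of same-numbered arrays ran from −0.47 to 0.37 over 4 pairs, and 2 of 8 arrays correlated best with their own number. The pairs numbered 2 (−0.47) and 4 (−0.39) each hold an array that stood apart, so these correlations cannot rule out pairing. With the replicate block 3 genes passed, namely YAP1, KRT10 and ANXA1, 2 of them (YAP1 and KRT10) at least 2-fold. CCN1 and CXCL10 did not pass there. WWTR1 differed by −0.62 with a limma adjusted p of 0.147. The camera adjusted p was 0.0653 for EWS-FLI1-repressed and 0.0559 for glycolysis genes. When 1 array was left out WWTR1 ranged from −0.65 to −0.58, with an adjusted p of 0.0515 without control replicate 1, and over all settings its adjusted p was 0.00245 to 0.147.

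With an estimated correlation 0 lists passed. The adjusted p was 0.132 for YAP/TAZ targets, 0.3 for EWS-FLI1-activated, 0.191 for EWS-FLI1-repressed, 0.403 for S phase, 0.191 for mitosis, 0.191 for actin, 0.191 for matrix, 0.191 for interferon, 0.3 for unfolded protein and 0.56 for glycolysis genes. By fry 3 passed, and the adjusted p was 0.166 for EWS-FLI1-activated, 0.0826 for EWS-FLI1-repressed, 0.166 for S phase, 0.0539 for mitosis, 0.0539 for actin, 0.0539 for matrix, 0.207 for unfolded protein and 0.415 for glycolysis genes. For EWS-FLI1-repressed genes it was 0.106 with the mean of a gene's clusters, 0.0653 without the pair, 0.0563 with the covariate, 0.0654 with the pair as a block, and 0.00949 to 0.149 leaving out 1 array. For glycolysis genes it was 0.088 after quantile normalization, 0.0974 with median centring, 0.194 with dim genes left out, 0.167 with the covariate, and 0.000214 to 0.302 leaving out 1 array. For matrix genes it was 0.0579 without the pair. The cause was not tested.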

Other observations

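Of the tests in this part, that of NF-kB target genes was written down before its result was seen. The test of interferon genes was chosen afterwards, and the amino acid supply list was altered after a first run. The genes named first were chosen after their values were seen.

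TNFAIP3, which encodes the ubiquitin-editing enzyme A20, rose by 0.63 (SE 0.058, limma adjusted p = 0.00559). NFKBIA, which encodes the inhibitor that keeps NF-kB in the cytoplasm, rose by 0.63 (SE 0.083, adjusted p = 0.0309). It passed in 2 of the 8 fits that left out 1 array and not with each array centred on its median (limma adjusted p = 0.0643). NR4A3, an orphan nuclear receptor and immediate early gene, rose by 0.59 (SE 0.049), and C3, a complement component, by 0.46 (SE 0.059). NR4A3 passed in 8 of the 8 fits that left out 1 array, but C3 in 1. The limma adjusted p of C3 was 0.0611 after quantile normalization and 0.162 with each array centred on its median. VCAM1, an adhesion molecule that NF-kB can induce, went the other way and fell by 0.56 (SE 0.076). This fall passed in 2 of the 8 fits that left out 1 array and not with each array centred on its median (limma adjusted p = 0.176). The microRNA gene MIR32 rose by 0.73 (SE 0.095, limma adjusted p = 0.0296) from a low level of 4.08 ± 0.14 (SD, n = 4). Its rise passed in 1 of the 8 fits that left out 1 array. The limma adjusted p was 0.0555 after quantile normalization and 0.108 with each array centred on its median.

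A hypothesis is that NF-kB targets moved up together. In a list of 24 other NF-kB targets 16 lay above 0, the median difference was 0.056, and fry gave p = 0.0227, while camera, which compares the list with other genes, gave p = 0.0614, or p = 0.155 with an estimated correlation. Of the 24 genes 17 lay below the median level of all genes, so this test rests largely on dim genes. By limma 0 of the 24 passed over all genes and 7 had an unadjusted p under 0.05, and the widest differences were 0.53 for CD83 and 0.29 for CCL20. Sensing of the siRNA mix as foreign RNA may also raise such genes. The mean of IFIT1, IFIT2, IFIT3, ISG15, MX1 and OASL differed by −0.020 (SE 0.035), or 0.0509 at 2 SE above. Their level of 4.08 lay below the median gene, so these genes are likewise too dim to decide it, and the controls also received an siRNA. Brighter interferon genes outside this test were higher, namely OAS3 by 0.38, RIGI by 0.29, IFIH1 by 0.34 and IFI6 by 0.78 (SE 0.38). None of these passed limma over all genes in the main fit. With the arrays that stood apart as a block OAS3 passed (limma adjusted p = 0.0166), as it did without them (0.0416). RIGI passed with the block (0.0469) but not without those arrays, IFI6 without them (0.0278) but not with the block, and IFIH1 in neither. These settings were chosen after seeing the data, and 7 of the 21 interferon genes lay below 0, so sensing of the siRNA mix stays open. An effect of losing YAP1 and TAZ stays open and was not separated from off-target effects, since 1 siRNA mix was used.

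SLC7A11, the cystine transporter, differed by −1.21 (SE 0.23, limma adjusted p = 0.091), from 12.08 ± 0.40 to 10.88 ± 0.37 (SD, n = 4 per group), and PSAT1, an enzyme of serine synthesis, by −0.95 (SE 0.35, adjusted p = 0.378). Neither passed in the main fit on all 8 arrays. For SLC7A11 that depended on the arrays that stood apart, while PSAT1 passed only when they were left out. With that pair as a block the adjusted p was 0.00695 for SLC7A11 and 0.0507 for PSAT1, and without the pair 0.0286 and 0.036. Over all 18 alternatives it ran from 0.00695 to 0.26 for SLC7A11, which passed in 4, and from 0.036 to 0.641 for PSAT1, which passed in 1. With SLC7A11, PSAT1, CHAC1 and ASNS set aside, 28 other ATF4-dependent genes, of which PHGDH is also among the EWS-FLI1-activated genes, had a median difference of −0.17, with 6 above 0. This list passed camera downward at its preset correlation only, with p = 2.7e-05 against p = 0.289 with an estimated correlation, and fry gave p = 0.3, so as for the stress response list whether the genes moved as a group stays open. The lowest single adjusted p belonged to SLC7A5, an amino acid transporter, with a difference of −0.65 (SE 0.15, adjusted p = 0.15). ASNS, whose values had been seen, was taken out of that list after a first run that did not pass fry either.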
